A study of Rattus norvegicus with 20 samples.

How the data were processed

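Liver RNA of Wistar Han rats was hybridised to Affymetrix rat genome arrays after amplification of 100 ng of total RNA, per the labels' protocols. Dams received 5 mL/kg of corn oil alone or with PBDE-47 at 10, 3 or 0.02 mg/mL, which gives 50, 15 or 0.1 mg/kg per day, from gestation day 6 to postnatal day 4. The deposited table holds log2 values of 31099 probe sets on 20 arrays, summarized with RMA (background correction, quantile normalization and median polish) per the submitters' processing notes. Its version, and whether all arrays were processed together, are not given in the sources used here. RMA values of bright probe sets are compressed near the top of the scale, and values near 2 to 4 carry mostly background, so folds are understated at both ends. Detection calls were not used here.

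Groups and replicate numbers were taken from the sample titles. The 57 control probe sets were left out, and 31042 were tested without a filter. GEO's platform annotation gives 1 gene symbol for 20826 of these, several for 436 and no gene name here for 9780. The single-symbol probe sets stand for 14217 genes, and 20758 of them were matched by gene ID in the RefSeq gene table of the GRCr8 assembly, where 0 symbols needed updating. That table was used only for names and for which genes neighbour each other. A probe set with several symbols was given no gene name.

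One linear model with a mean for each of the 4 groups was fitted to the log2 values with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), because the series compares each dose with vehicle in 1 analysis at a false discovery rate of 0.05. That analysis used R/maanova, which was not used here. Every adjusted p for a probe set is from limma with Benjamini-Hochberg adjustment per contrast, called under 0.05. The contrasts were each dose against vehicle, a slope over the dose order, 50 against 15 mg/kg and 15 against 0.1 mg/kg. Tests are two-sided, and intervals are 95% intervals of the fit.

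Before the data were examined, 35 gene lists were written down, covering receptor responses, metabolism, stress, sample handling, cell types that a liver sample can hold, and Y-linked genes. Each gene was represented by its single-symbol probe set with the highest mean. The 34 lists with at least 4 measured members were tested with limma's camera at a preset correlation of 0.01, with adjustment over 102 tests (34 lists and 3 doses). Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in one direction, were alternatives. Of the calls, only the CAR and PXR list at 15 and 50 mg/kg held with an estimated correlation.

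Genes were named by a rule fixed before the data were examined: per dose, the 12 largest rises and 12 largest falls among called single-symbol probe sets, the 3 smallest p in each direction where none passed, up to 4 members of each described list with the smallest p at 50 mg/kg, and a fixed set of index genes. Unnamed loci were named only if among the 5 largest. Genes named at 15 against 0.1 mg/kg and in the trend are from that set.

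The code was tested on simulated data for the comparison of 50 mg/kg with vehicle over 31042 probe sets. It recovered 64% of changes of 0.5 log2 units, 90% of those of 1 and 100% of those of 2 and of 3, with 4 false calls, and called 0 at the unchanged doses. The simulated noise was Gaussian and independent between probe sets. It lacked the variation that genes share between the real arrays, so these rates need not hold for them. Unchanged groups that share the vehicle arrays were simulated 100 times from Gaussian mixtures of whole-array residuals, with the error of the vehicle mean included. Other splits of the arrays were refitted 100 times per comparison, and list means were compared by exact permutation.

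Alternatives tried were a block for the replicate number or for the leading digit of the array description number, only the groups compared, another quantile normalization, equal medians, filters at a mean of 6 or 5, no variance shrinkage, an intensity trend with robust shrinkage, array weights, 1 probe set per gene, adjustment over all contrasts, and each array left out. After seeing the data, 3 were added: covariates from the muscle, pancreas and erythroid lists, leaving out arrays whose muscle or pancreas list mean was over 2 log2 units above the lowest array, and the 3' to 5' difference of the beta-actin controls as a covariate. Random choices of as many arrays per group served as a reference for the left-out fit. That difference ranged from 1.22 to 2.43. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.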

Results

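Messenger RNA was measured in liver at postnatal day 4 in a study of PBDE-47, a brominated diphenyl ether flame retardant given by gavage in corn oil from gestation day 6. The 20 Affymetrix arrays form 4 groups of 5: vehicle, 0.1, 15 and 50 mg/kg per day. The labels tie the dosing to dams and do not say whether a given liver came from a dam or a pup. The mean of the fetal liver list, which includes Afp, ranged from 10.27 to 10.9 over the arrays, whose medians were 5.605 to 5.648. Such levels of fetal genes on every array argue against livers of adult dams. The number of arrays limits the precision. The labels do not state that the arrays of a group came from separate animals, and they give no litter, so litter was not modelled. The p-values therefore measure the spread between these samples, which may differ from that between dosed dams.

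The comparison of 50 mg/kg with vehicle asked which liver transcripts differ at the highest dose. The 3 largest rises among the named genes were of cytochrome P450 genes. Cyp1a1, a monooxygenase regulated by the aryl hydrocarbon receptor, rose 11.0-fold (log2 change 3.46, SE 0.22, adjusted p = 1.43e-08, n = 5 per group). Cyp2c7 rose 9.26-fold (log2 change 3.21, SE 0.35, adjusted p = 4.93e-05), and Cyp2a3 rose 7.17-fold (log2 change 2.84, SE 0.40, adjusted p = 0.000841). Aldh1a1, which oxidizes retinaldehyde, rose 3.97-fold (log2 change 1.99, SE 0.235, adjusted p = 0.000116).

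The other named rises were Dnajb3 (log2 change 1.89), Cyp2c6v1 (1.80), the homeobox gene Meox2 (1.75), the carboxylesterase Ces2c (1.72), Ddc (1.57), the glucuronosyltransferase Ugt2b10 (1.56) and Alas1 (1.52), and Abcc3, which rose 2.83-fold. Ddc encodes aromatic amino acid decarboxylase, Alas1 the first enzyme of heme synthesis and Abcc3 an efflux transporter. For each of these 12 rises all 5 arrays at 50 mg/kg lay above every vehicle array. A further, dimmer probe set of Ddc did not pass (log2 change 0.48, adjusted p = 0.210). Dnajb3 neighbours the Ugt1a genes, whose probe sets 1370613_s_at and 1387759_s_at had log2 changes of 0.28 (adjusted p = 0.0373) and 0.16 (adjusted p = 0.609, and 0.07 without vehicle replicate 3). The first of these calls ended without any 1 of vehicle replicates 2, 3 and 4 or replicates 1, 3, 4 and 5 at 50 mg/kg. Probe set 1371076_at, assigned by the annotation to several genes of the Cyp2b subfamily, so that no gene is named, rose 4.40-fold (log2 change 2.14, SE 0.134) to a mean of 14.02, near the top of the scale. The index genes Cyp2b1, Cyp2b2, Ugt1a1 and Ugt1a6 had no probe set of their own.

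**Figure D1:**
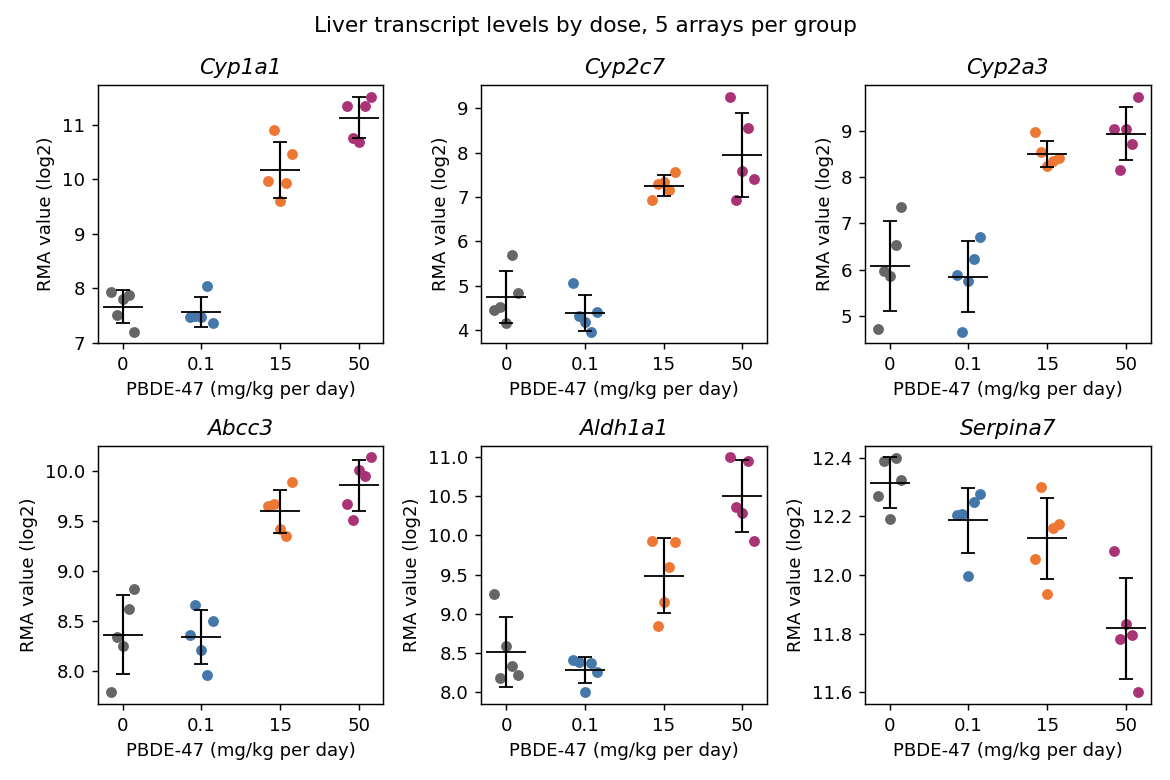
RMA values (log2) of 6 genes on the vertical axes against the dose of PBDE-47 in mg/kg per day on the horizontal axes. Points are single arrays, 5 per group, bars are the mean and SD, and Cyp1a1 averages 7.67 in vehicle and 11.13 at 50 mg/kg, and Serpina7 averages 12.31 and 11.82.

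Across the array 290 probe sets changed at 50 mg/kg, 182 higher and 108 lower, among 31042 tested with limma. Of these 98 changed at least 1.5-fold. The single-symbol probe sets among all 290 stand for 233 genes. The count fell to 180 without vehicle replicate 2, 177 without vehicle replicate 3, 137 without vehicle replicate 4, and 181, 106 and 152 without replicates 3, 4 and 5 at 50 mg/kg. A fit of only the 2 groups compared called 89 and adjustment over all contrasts together 153. Of the fits chosen after seeing the data, that with the actin 3' to 5' difference as a covariate called 193. The fit without the arrays that carried muscle or pancreas transcripts called 3.

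Falls at 50 mg/kg were smaller than the leading rises. The unnamed locus LOC102554026 fell by 1.44 on the log2 scale (SE 0.27, adjusted p = 0.0131), and Nfkbiz, a nuclear regulator of NF-kappaB target genes, fell by 1.06 (SE 0.21, adjusted p = 0.0167). The other named falls were the vasopressin receptor gene Avpr1a (log2 change -1.06), Depp1 (-1.04), the growth factor gene Gdf11 (-1.03), Qsox1 (-1.02), Rasd2 (-0.99), Gen1 (-0.86), the histone gene H4f3 (-0.84), Ms4a6a (-0.78), the thiamine transporter gene Slc19a2 (-0.75) and Gas6 (-0.74). A further probe set of Qsox1 also fell (log2 change -0.97, adjusted p = 0.0384), a call that ended without vehicle replicates 2, 4 or 5 or any 1 of replicates 1, 2, 4 and 5 at 50 mg/kg. Further probe sets did not pass for Ms4a6a (-0.27), Gas6 (0.16 and -0.05), Gdf11 (0.11), Rasd2 (0.00) and Nfkbiz (0.21, 95% interval 0.06 to 0.35), so that for Gdf11, Nfkbiz and, barely, Rasd2 they had the opposite sign and for Gas6 1 of them did. That of Gdf11 was 0.05 without replicate 3 at 50 mg/kg. The positive one of Gas6 was 0.09 without vehicle replicate 1 or replicate 1 at 50 mg/kg, and the other was 0.03 without vehicle replicate 4. The calls of LOC102554026 and Nfkbiz, 2 of the 12 falls, held when any single array was left out. The other 10 all ended without replicate 4 at 50 mg/kg, and those of Avpr1a, Gdf11, Qsox1, H4f3, Ms4a6a, Slc19a2 and Gas6 also without vehicle replicate 4. Without the arrays that carried muscle or pancreas transcripts the calls of LOC102554026 and Nfkbiz ended too. Their log2 changes were then -1.06 and -1.14, with 2 arrays kept at 50 mg/kg. The call of H4f3 also ended with the replicate number as a block.

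Targets of the nuclear receptors CAR and PXR rose as a group at 50 mg/kg. Of 22 measured members 12 rose, 0 fell and 10 did not pass, or 19 rose adjusted over the list alone, and the list's adjusted p was 3.36e-27. That call held with an estimated correlation (adjusted p = 0.000375 with an estimated correlation). Members included Cyp2c6v1, Alas1, Cyp2c7 and the epoxide hydrolase gene Ephx1, which rose 2.28-fold (log2 change 1.19, SE 0.12). Cyp3a23-3a1 rose 1.71-fold (log2 change 0.78, SE 0.12, adjusted p = 0.00241), and Cyp3a2 had a log2 change of 0.17 (adjusted p = 0.228) from a vehicle mean of 13.57, near the top of the scale. The median member was 1.75-fold higher.

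**Figure D2:**
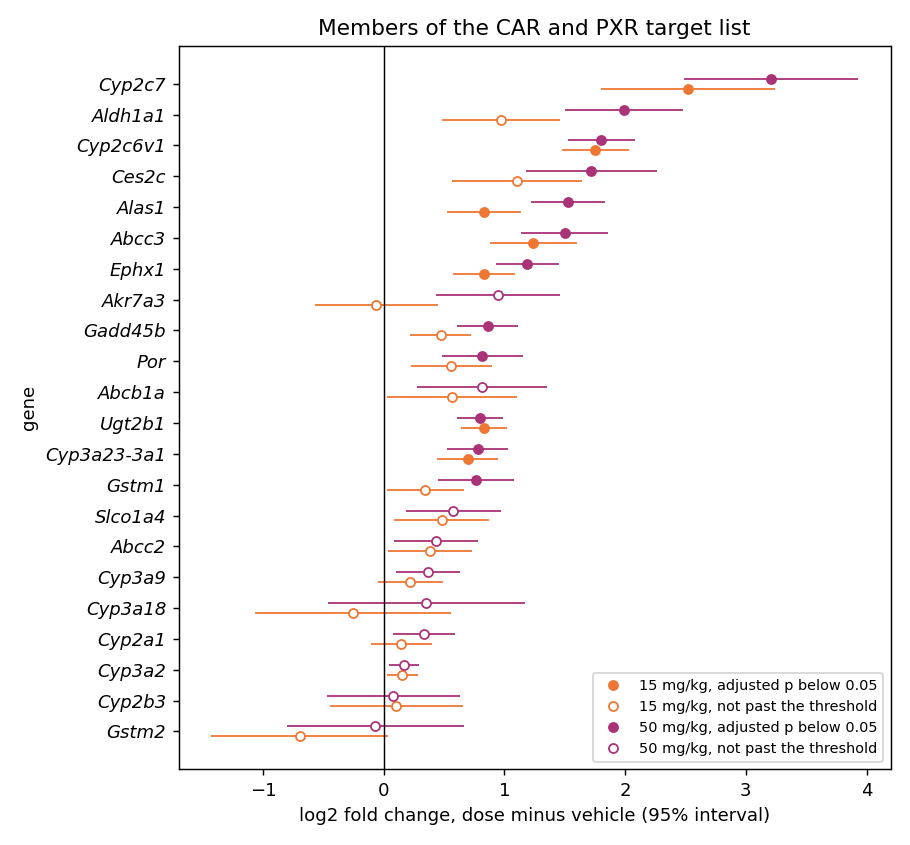
Log2 fold change against vehicle, with 95% intervals, on the horizontal axis for the 22 measured members of the CAR and PXR target list on the vertical axis. Orange points are 15 mg/kg, purple points 50 mg/kg and filled points passed the test, and of the members 7 rose at 15 mg/kg and 12 at 50 mg/kg, with Cyp2c7 at 2.52 and 3.21.

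Markers of Kupffer cells, the resident macrophages of liver, were lower at 50 mg/kg. Of 9 measured members 4 fell and 5 did not pass (7 fell adjusted over the list alone), with an adjusted p for the list of 1.93e-09, lost as adjusted p = 0.142 with an estimated correlation. The complement genes C1qb and C1qc fell by 0.57 (SE 0.10) and 0.55 (SE 0.12) on the log2 scale, the scavenger receptor gene Cd163 fell by 0.48 (SE 0.10), and Cd68 fell by 0.48 (SE 0.10). The list mean was 9.81 ± 0.10 (SD, n = 5) in vehicle and 9.37 ± 0.17 (SD, n = 5) at 50 mg/kg, a log2 difference of -0.44 with an exact two-sided permutation p of 0.00794, the smallest that 5 against 5 arrays allow. The endothelial list mean differed by -0.01 (exact permutation p = 0.833). Both permutation tests were chosen after the list results were seen, and their p-values are not adjusted over the 34 lists. Of other immune cell lists, neutrophil genes had a median log2 change of -0.51 (adjusted p = 0.0216, and 0.594 with an estimated correlation). B cell genes had one of -0.21 (adjusted p = 0.0626). In each of these 2 lists 4 of 4 members were lower and 0 passed over all probe sets. T and NK cell genes had a median of -0.04 (adjusted p = 0.113). The call of C1qb held when any single array was left out. Those of C1qc, Cd163 and Cd68 each ended without vehicle replicate 3, vehicle replicate 4 or replicate 4 at 50 mg/kg. That of C1qc ended without any 1 of the 10 arrays, and with the leading digit of the description number as a block. Without the arrays that carried muscle or pancreas transcripts these calls ended, that of C1qb included, with 2 arrays kept at 50 mg/kg. The log2 changes were then -0.53 for C1qb, C1qc and Cd163 and -0.54 for Cd68.

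In the other lists that passed at 50 mg/kg few members passed alone, and none of these calls held with an estimated correlation. That correlation was 0.0054 in the NRF2 list and 0.026 in the AhR list, against 0.71 in the cholesterol synthesis list. In the AhR list 1 of 9 members rose, Cyp1a1 (3 adjusted over the list alone; adjusted p = 0.142 with an estimated correlation), and Cyp1a2 had a log2 change of 1.06 (SE 0.33, adjusted p = 0.155). Cyp1a2 passed without vehicle replicate 5 (1.37, adjusted p = 0.0313) or replicate 2 at 50 mg/kg (1.35, adjusted p = 0.0424), with a range of 0.0313 to 0.813 over its alternatives, and was at 0.61 without the arrays that carried muscle or pancreas transcripts. In the NRF2 list 2 of 17 rose, the glutathione transferase gene Gsta3 (log2 change 0.81) and the malic enzyme gene Me1 (0.83); 7 rose and 1 fell adjusted over the list alone (list adjusted p = 0.00428, and adjusted p = 0.0865 with an estimated correlation), with Nqo1 at 0.63 (adjusted p = 0.213). In the PPARA and fatty acid oxidation list 3 of 27 rose, Pdk4 (1.04), Ehhadh (0.87) and Cpt2 (0.54; the calls of Ehhadh and Cpt2 ended without replicates 2, 3, 4 or 5 at 50 mg/kg or vehicle replicates 3 or 4, and that of Ehhadh with the replicate number as a block), with 5 adjusted over the list alone and adjusted p = 0.326 with an estimated correlation. In the cholesterol synthesis list all 20 members had a positive sign and 1, Pmvk, rose (log2 change 0.56, a call that ended without vehicle replicates 1 or 4 or replicates 1, 3, 4 or 5 at 50 mg/kg), with 8 adjusted over the list alone and adjusted p = 0.612 with an estimated correlation. The mean change of the cholesterol synthesis list was 0.41, and 0.21 without vehicle replicate 1. Further probe sets also rose at 50 mg/kg for Pdk4 (log2 change 0.53, adjusted p = 0.00577) and Me1 (0.84, adjusted p = 0.018). That call of Pdk4 held when any single array was left out. That of Me1 ended without vehicle replicate 2 or replicate 4 at 50 mg/kg.

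Among periportal hepatocyte genes 1 of 10 fell, the urea cycle gene Asl (log2 change -0.55, adjusted p = 0.0488, a call that held only without vehicle replicate 4 or replicate 2 at 50 mg/kg among the fits that leave out 1 array), with 4 adjusted over the list alone and adjusted p = 0.246 with an estimated correlation. A further probe set of Asl also fell (log2 change -0.59, adjusted p = 0.0444). Among the fits that leave out 1 array its call held only without vehicle replicate 4. Of the 19 acute phase genes 0 passed over all probe sets, and 1 rose and 5 fell adjusted over the list alone (list lower, adjusted p = 0.000138, and adjusted p = 0.579 with an estimated correlation). Its members with the smallest p included A2m (log2 change -0.41, adjusted p = 0.0526, and 0.0361 to 0.675 over its alternatives, the lowest with an intensity trend) and Cxcl1 (-1.46, adjusted p = 0.137). Without vehicle replicate 4 Cxcl1 was at -0.95, and the mean change of the acute phase list went from -0.33 to -0.17. Of the 4 neutrophil genes 0 passed, with Lcn2 at -1.09 (adjusted p = 0.472), 0 adjusted over the list alone, a list adjusted p of 0.0216, and adjusted p = 0.594 with an estimated correlation. That call ended without vehicle replicate 4 (adjusted p = 0.0895) or replicate 4 at 50 mg/kg (adjusted p = 0.128), with a range of 0.00626 to 0.594 over its alternatives. Without vehicle replicate 4 Lcn2 was at -0.43, and without replicate 4 at 50 mg/kg the mean change of the neutrophil list went from -0.64 to -0.38. With fry the cholesterol synthesis and acute phase calls ended (adjusted p = 0.196 for each), as did the neutrophil call (0.228). The AhR (fry adjusted p = 0.000276), NRF2 (0.000628), PPARA (0.0152) and periportal (0.0246) calls held with fry. The AhR call ended without the arrays that carried muscle or pancreas transcripts (0.0562), a fit that called 15 lists. In 100 splits of the same 10 arrays, 12 called at least as many lists as the 9 found here, so that the number of lists called with the preset correlation was within what regrouping gives.

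The thyroid and retinoid lists did not pass at 50 mg/kg. In the thyroid list (adjusted p = 0.925) Me1 rose and Serpina7, which encodes thyroxine-binding globulin, fell by 0.50 on the log2 scale (SE 0.08, adjusted p = 0.00542); 2 rose and 1 fell adjusted over the list alone. Its median change was -0.01 and its mean change 0.01. Dio1 had a log2 change of -0.33 (adjusted p = 0.551), which was -0.18 without vehicle replicate 1 and -0.22 without replicate 4 at 50 mg/kg. Thrsp had a log2 change of 0.32 (adjusted p = 0.209). In the retinoid list (adjusted p = 0.602) 1 of 11 members rose, Aldh1a1, with 1 higher and 1 lower adjusted over the list alone, a median of -0.01 and a mean of 0.20. In the lipogenesis list (adjusted p = 0.155) 1 of 18 rose, Me1, with 3 higher and 1 lower adjusted over the list alone, and the pyruvate kinase gene Pklr had a log2 change of -0.46 (adjusted p = 0.104). A further probe set of Pklr passed (log2 change -0.49, adjusted p = 0.0481), a call that held only without vehicle replicate 4 or replicate 2 at 50 mg/kg among the fits that leave out 1 array. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a log2 change of 0.29 (adjusted p = 0.659), which was 0.15 without vehicle replicate 1, 0.45 without vehicle replicate 2, and 0.19 and 0.45 without replicates 3 and 4 at 50 mg/kg. Afp and Alb averaged 14.31 and 14.78 at 50 mg/kg, near the highest values of the arrays, where a change would be compressed.

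At 15 mg/kg the same question gave fewer calls, and the largest named rises were again of Cyp2c7, Cyp1a1 and Cyp2a3. Cyp2c7 rose 5.73-fold (log2 change 2.52, SE 0.35, adjusted p = 0.00252), Cyp1a1 5.66-fold (log2 change 2.50, SE 0.22, adjusted p = 3.18e-06) and Cyp2a3 5.33-fold (log2 change 2.41, SE 0.40, adjusted p = 0.0134). The other named rises were Meox2 (log2 change 1.85), Cyp2c6v1 (1.75), Ugt2b10 (1.41), Abcc3 (1.24), Stbd1 (1.16), Tsku (1.13), Ugt2b1 (0.83), Ephx1 (0.83) and Alas1 (0.83). Probe set 1371076_at of the Cyp2b subfamily rose 3.98-fold. Plaat3 (-0.66), the splicing factor gene Sf3b1 (-0.63), the mitochondrial carrier gene Slc25a22 (-0.45) and Selenok (-0.28) fell. The 2 further probe sets of Sf3b1, both brighter, did not pass (-0.29, adjusted p = 0.375, and -0.12, adjusted p = 0.559), and were at -0.185 and -0.05 without vehicle replicate 1.

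In all 36 probe sets changed at 15 mg/kg, 29 higher and 7 lower, and 27 of them changed at least 1.5-fold. The count was 20, 22 and 23 without vehicle replicates 3, 4 and 5, 16 and 14 without replicates 4 and 5 at 15 mg/kg, and 11 in a fit of only the 2 groups. Of the fits chosen after seeing the data, that with muscle, pancreas and erythroid covariates called 20. That without the arrays that carried muscle or pancreas transcripts called 3. Of the 12 named rises 9 held when any single array was left out, the exceptions being Meox2, Tsku and Alas1, each of which ended without replicates 4 or 5 at 15 mg/kg. The Meox2 call also ended with the leading digit of the description number as a block. Of the 4 named falls 0 held, Plaat3, Sf3b1, Slc25a22 and Selenok each ending without replicate 5 at 15 mg/kg, and Selenok also with the replicate number as a block.

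CAR and PXR targets rose as a group at 15 mg/kg, with 7 of 22 members higher, 14 adjusted over the list alone, and a list adjusted p of 2.41e-17 (adjusted p = 0.00263 with an estimated correlation). The AhR list (adjusted p = 0.0287, and adjusted p = 0.246 with an estimated correlation) had 1 member that rose, Cyp1a1, and 2 adjusted over the list alone. Of the 10 periportal genes 0 passed over all probe sets and 4 fell adjusted over the list alone (list adjusted p = 2.22e-05, and adjusted p = 0.142 with an estimated correlation). Of the 9 Kupffer genes 0 passed and 2 fell adjusted over the list alone (list adjusted p = 0.000731, and adjusted p = 0.538 with an estimated correlation). Cell cycle genes, 0 of 27 passing in either adjustment, had a median log2 change of -0.19 (adjusted p = 0.000103, and adjusted p = 0.729 with an estimated correlation), and the list was no longer called with the covariates (adjusted p = 0.372). The PPARA list (adjusted p = 0.0301) and the acute phase list (adjusted p = 0.0329) had 0 members past the test over all probe sets, and 1 and 0 higher adjusted over the list alone, and gave adjusted p = 0.679 with an estimated correlation and adjusted p = 0.750 with an estimated correlation. The AhR call ended without vehicle replicate 5 (adjusted p = 0.0586) or replicate 2 at 15 mg/kg (0.143), the PPARA call without vehicle replicates 3 (0.0781) or 4 (0.259) or replicates 1 (0.212) or 4 (0.0808) at 15 mg/kg, and the acute phase call without vehicle replicate 4 (0.778) or replicates 1 (0.0783) or 3 (0.120) at 15 mg/kg. The acute phase call also ended with the replicate number as a block (0.0510), with only probe sets of a mean of at least 6 (0.115), with the covariates (0.265) and without the arrays that carried muscle or pancreas transcripts (0.0540). With the mean of all probe sets per gene the AhR (0.106) and PPARA (0.0887) calls ended, and the PPARA call also with the covariates (0.0830). Without vehicle replicate 4 the mean change of the acute phase list went from -0.18 to -0.02, and that of the cell cycle list went from -0.20 to -0.12 without vehicle replicate 3 or replicate 4 at 15 mg/kg. Exocrine pancreas genes had a median log2 change of 1.18 with 0 of 8 passing and 1 higher adjusted over the list alone (list adjusted p = 0.000731, and adjusted p = 0.580 with an estimated correlation), and their list mean was 6.89 and 7.05 on replicates 3 and 5 and 4.01 to 4.19 on the other arrays at 15 mg/kg (mean change 1.15, and 0.74 or 0.70 without replicate 3 or 5). Fry called 3 lists, without the acute phase, cell cycle, pancreas, Kupffer and PPARA lists, and the fit with covariates called 5, without the pancreas list, which is itself a covariate and so is not tested there. In 100 splits of these arrays 34 called at least as many lists as the 8 called here.

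At 0.1 mg/kg limma called 0 probe sets, with 2134 at an unadjusted p under 0.05 where chance gives 1552, and a smallest adjusted p of 0.229. Fits without variance shrinkage and with an intensity trend also called 0, adjustment over all contrasts called 6, and leaving out vehicle replicate 4 or replicate 3 at 0.1 mg/kg called 1 each. Cyp1a1 had a log2 change of -0.09 (95% interval -0.55 to 0.36) and Abcc3 of -0.03 (-0.39 to 0.33). The genes with the smallest p were Tgfa (log2 change 0.57), Ctsm (0.33) and Nhsl2 (0.33) above vehicle and Arl6ip6 (-0.62), Pcmtd2 (-0.49) and Cpsf7 (-0.44) below, all at adjusted p = 0.429. Ctsm read 2.78 to 3.09 in vehicle and Arl6ip6 3.80 to 3.97 at 0.1 mg/kg, where values carry mostly background. Further probe sets read 0.53 for Tgfa, -0.18 for Pcmtd2, -0.05 for Nhsl2, opposite in sign, and -0.05, -0.07 and 0.03 for Cpsf7, the last opposite in sign. The sign of that of Nhsl2 turned without vehicle replicate 3 or replicate 4 at 0.1 mg/kg, and for Cpsf7 1 turned without vehicle replicate 3 and 1 without replicate 5 at 0.1 mg/kg.

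Of the gene lists 6 passed at 0.1 mg/kg with the preset correlation and 0 with an estimated one. No member of these 6 passed, over all probe sets or adjusted over the list alone. Skeletal muscle genes had a median log2 change of 1.68 (adjusted p = 0.619 with an estimated correlation), stellate cell and fibroblast genes 0.30 (adjusted p = 0.580 with an estimated correlation), exocrine pancreas genes 0.71 (adjusted p = 0.679 with an estimated correlation), acute phase genes -0.14 (adjusted p = 0.626 with an estimated correlation), periportal genes -0.16 (adjusted p = 0.412 with an estimated correlation) and Kupffer genes -0.06 (adjusted p = 0.679 with an estimated correlation). Each call ended without at least 1 array: the acute phase list without vehicle replicate 4 (adjusted p = 0.335), the stellate list without vehicle replicate 1 (0.0520), and at 0.1 mg/kg the periportal list without replicate 3 (0.0557) and the pancreas list without replicate 2 (0.554). The muscle call ended without replicates 1 (0.0778), 4 (0.194) or 5 (0.0627) at 0.1 mg/kg or vehicle replicates 3 (0.0781) or 5 (0.0723), and the Kupffer call without replicates 2 (0.554) or 3 (0.116) at 0.1 mg/kg or vehicle replicates 2 (0.0643), 4 (0.114) or 5 (0.0961). The mean change went from -0.20 to -0.04 for the acute phase list without vehicle replicate 4, from -0.20 to -0.12 for the periportal list without vehicle replicate 1, and from 0.64 to 0.08 for the pancreas list without replicate 2 at 0.1 mg/kg. It went from 1.51 to 2.43 for the muscle list without vehicle replicate 2 and to 0.90 without replicate 4 at 0.1 mg/kg, and from -0.10 to -0.01 and -0.16 for the Kupffer list without replicates 2 and 5 at 0.1 mg/kg. Fry called 0 lists. With the leading digit of the description number as a block the pancreas (0.0617) and Kupffer (0.0625) calls ended, the latter also with another quantile normalization (0.0863) or only probe sets of a mean of at least 6 (0.0933). The stellate call ended with the covariates (0.454) and without the arrays that carried muscle or pancreas transcripts (0.196). These fits do not test the muscle and pancreas lists, from which they were built. In 100 splits of the arrays 54 called at least as many lists.

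Transcripts of muscle and pancreas varied between arrays within groups. The skeletal muscle list mean was 8.50 on vehicle replicate 2, 6.99, 8.76 and 8.13 on replicates 1, 4 and 5 at 0.1 mg/kg, 8.75 on replicate 3 at 15 mg/kg and 6.54, 5.90 and 7.05 on replicates 1, 3 and 4 at 50 mg/kg, against 3.76 to 5.00 on the other arrays. The exocrine pancreas list mean was 7.00 on replicate 2 at 0.1 mg/kg. With muscle, pancreas and erythroid list means as covariates, the CAR and PXR list (adjusted p = 2.66e-25) and the Kupffer list (adjusted p = 1.82e-10) still passed at 50 mg/kg, and the neutrophil list did not (adjusted p = 0.0830). Without the arrays that carried these transcripts, only Cyp1a1 and Cyp2c6v1 of the named genes kept their calls, at 15 and 50 mg/kg, in a fit with 2 arrays at 50 mg/kg. The changes themselves were a median of 0.963 times the original over the 54 named calls, and 2 moved by over 1.5 times, Rasd2 (from -0.99, SE 0.217, to -0.54, SE 0.281) and Gen1 (from -0.86, SE 0.168, to -0.54, SE 0.170), while the SE was a median of 1.30 times the original. Alas1 at 50 mg/kg went from 1.52 (SE 0.146) to 1.57 (SE 0.238) and Ephx1 from 1.19 (SE 0.124) to 1.13 (SE 0.197). Cyp1a1 at that dose went from 3.46 (SE 0.217) to 3.43 (SE 0.312). Other leading rises there became smaller, Cyp2c7 from 3.21 (SE 0.345) to 2.38 (SE 0.344) and Aldh1a1 from 1.99 (SE 0.235) to 1.55 (SE 0.327). Of 100 random choices of as many arrays per group, also chosen after seeing the data, 9 gave as few probe sets at 50 mg/kg (median 10, range 3 to 197) and 19 as few named calls (median 8).

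**Figure D3:**
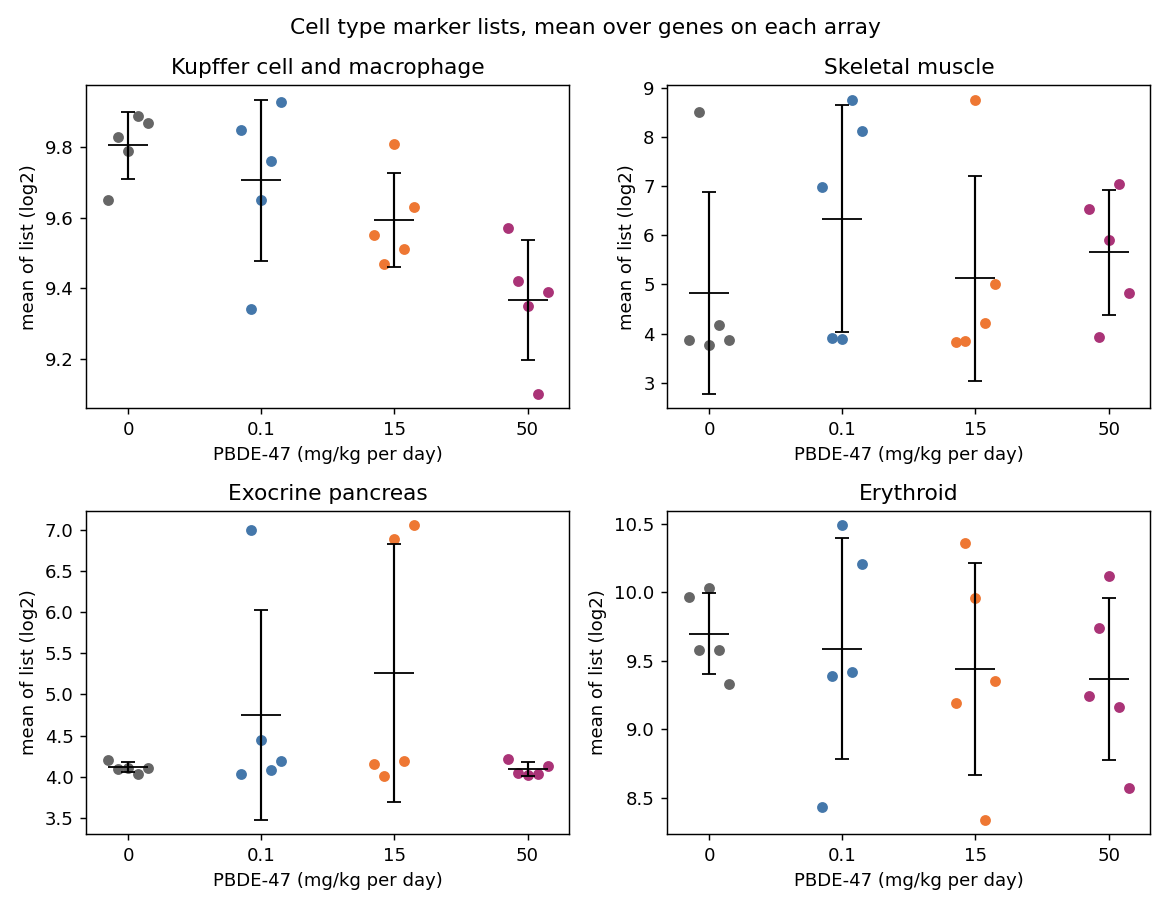
Mean log2 value over the genes of 4 cell type marker lists on the vertical axes against the dose of PBDE-47 in mg/kg per day on the horizontal axes. Points are single arrays, 5 per group, bars are the mean and SD, and the Kupffer list averages 9.81 in vehicle and 9.37 at 50 mg/kg, while the skeletal muscle list ranges from 3.76 to 8.50 within vehicle.

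A linear slope over the order of the 4 doses asked which transcripts tend up or down with dose, which does not test a change at each dose. The fitted slope, in log2 units per place in the order, was 1.30 for Cyp1a1 (SE 0.07, adjusted p = 5.92e-10), 1.25 for Cyp2c7 (SE 0.11, adjusted p = 1.92e-06), 1.12 for Cyp2a3 (SE 0.13), 0.73 for Cyp2c6v1 (SE 0.04) and 0.72 for Aldh1a1 (SE 0.07). Cyp1a1 differed by -0.09 between 0.1 mg/kg and vehicle, 2.60 between 15 and 0.1 mg/kg and 0.96 between 50 and 15 mg/kg. For Cyp2c6v1 the difference was 1.90 between 15 and 0.1 mg/kg and 0.05 between 50 and 15 mg/kg. LOC102554026 had a slope of -0.48 (SE 0.09, adjusted p = 0.00553). The trend was called for 449 probe sets, 298 with a positive and 151 with a negative slope. The count was 282 without vehicle replicate 4, 232 and 284 without replicates 4 and 5 at 50 mg/kg, 199 without the 0.1 mg/kg group and 203 with adjustment over all contrasts. It was 5 without the arrays that carried muscle or pancreas transcripts, a fit chosen after seeing the data.

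Tested against each other, 50 and 15 mg/kg differed in 0 probe sets with limma (smallest adjusted p 0.525, 1749 at an unadjusted p under 0.05), also without variance shrinkage, and in 5 with adjustment over all contrasts. Alas1 was 0.69 log2 units higher at 50 than at 15 mg/kg (95% interval 0.39 to 1.00, adjusted p = 0.525), Aldh1a1 1.02 higher (0.53 to 1.51, adjusted p = 0.655) and Cyp1a1 0.96 higher (0.50 to 1.41, adjusted p = 0.655). Cyp2c6v1 differed by 0.05 (-0.23 to 0.32) between means of 13.69 and 13.74, near the top of the scale, where a difference would be compressed. Between 15 and 0.1 mg/kg 28 probe sets differed, 27 higher and 1 lower, led by Cyp2c7 (log2 difference 2.88, adjusted p = 0.000337), Cyp2a3 (2.65, adjusted p = 0.00419), Cyp1a1 (2.60, adjusted p = 1.67e-06) and Cyp2c6v1 (1.90, adjusted p = 1.79e-07). That count was 0 without the arrays that carried muscle or pancreas transcripts, a fit chosen after seeing the data that keeps 1 array at 0.1 mg/kg and 3 at 15 mg/kg.

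Calls at 15 and 50 mg/kg shared 32 probe sets, 27 higher and 5 lower, Cyp1a1, Cyp2c7 and Abcc3 among them. Both comparisons use the same vehicle arrays. In 100 simulations of unchanged groups against those arrays the shared count had a median of 0 and a highest value of 4, and independent lists of these sizes would share 0.170 higher and 0.0244 lower. The vehicle arrays were also split between the comparisons, over 20 splits. With fewer vehicle arrays each, these called 7 to 69 probe sets at 15 mg/kg and 38 to 275 at 50 mg/kg. The shared count then had a median of 9 and ranged from 5 to 17. It was 18, 19 and 20 without vehicle replicates 3, 4 and 5 and 14 and 13 without replicates 4 and 5 at 15 mg/kg. In fits chosen after seeing the data it was 18 with the covariates and 3 without the arrays that carried muscle or pancreas transcripts. Across probe sets, which are not independent replicates, the log2 changes at both doses had a correlation of 0.684 (simulated mean 0.462; 0.128 to 0.343 with split vehicle arrays, 2 or 3 per comparison) and a covariance of 0.0203 (simulated mean 0.00899; median 0.0106 with split vehicle arrays). Of the 290 probe sets called at 50 mg/kg, 289 had the same sign at 15 mg/kg and 210 at 0.1 mg/kg. As many probe sets with the smallest p in the simulations gave a median of 280 (range 85 to 290) at 15 mg/kg. At 0.1 mg/kg they gave a median of 279.5 (range 40 to 290), so that both counts lie within what unchanged groups gave.

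As a check of the labels, which give all animals as female, the Y-linked gene Eif2s3y read 8.79 to 9.48 and 1 probe set of Uty 8.65 to 9.20 on the 20 arrays, with a further Uty probe set at 2.95 to 3.60. The 4 probe sets of Xist, the X-inactivation transcript, read 2.49 to 3.62, under the lower quartile of every array.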

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

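Of 464 sets of 5 values (named genes and described lists in each group), 45 held an array far from the other 4 of its group, where chance gives about 1 in 20, or 23.2. Genes of one list vary together, so these are not independent.

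Vehicle replicate 1 stood apart in 7 sets. It was low in Alas1 (9.62), Mvk (7.71), Myh4 (2.38) and the cholesterol synthesis list mean (8.52, with the other vehicle arrays at 9.47 to 9.60), and high in Cyp3a23-3a1 (13.42), Cpt2 (10.34) and the periportal list mean (11.59). Without it the cholesterol synthesis list at 50 mg/kg had an adjusted p of 0.00110.

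Vehicle replicate 4 was high in A2m (13.89), Lbp (11.99), Lcn2 (13.02), Rdh7 (12.20) and the acute phase list mean (11.04, with the others at 10.15 to 10.38). Without it the acute phase list at 50 mg/kg had an adjusted p of 0.0147. Replicate 2 at 15 mg/kg was also high in the acute phase list mean (10.52), and replicate 4 at 50 mg/kg was low in it (9.91), in C1qc (8.90) and in S100a9 (11.52).

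Muscle genes were high on vehicle replicate 2, with Acta1 at 12.23, Myl11 at 11.56, Tnnt3 at 9.60 and the muscle list mean at 8.50. That array was also high in Col1a2 (11.00) and low in Pdk4 (8.64). Replicate 3 at 15 mg/kg was high in Myl11 (11.86), Tnnt3 (10.13), the muscle list mean (8.75) and C1qb (10.25), and low in Gsta3 (11.30). Pancreas genes were high on replicate 2 at 0.1 mg/kg, with Prss1 at 6.51, Cel at 7.60 and the pancreas list mean at 7.00. That array was high in LOC102554026 (7.46) and low in Ttr (14.12).

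Single values lay low for Ctsm (2.78) and Rarb (8.39) on vehicle replicate 3 and for Cyp1b1 on vehicle replicate 5 (4.30). At 0.1 mg/kg, replicate 3 was low in Serpina7 (12.00), replicate 4 was high in Cyp1a1 (8.05) and low in Lcn2 (9.71), and replicate 5 was low in Arl6ip6 (3.80) and Ddc (8.05) and high in the retinoid list mean (8.25). Replicate 4 at 15 mg/kg was low in Depp1 (7.07) and Cyp1b1 (4.74). At 50 mg/kg, replicate 1 was low in Mvd (7.03) and replicate 3 in Nhsl2 (4.08).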

How the results depend on the processing

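The covariates from muscle, pancreas and erythroid lists, the fit without arrays with muscle or pancreas transcripts, the actin covariate and all alternatives for the shared calls except the split controls were chosen after seeing the data. Of 128 counts in settings that keep every array or drop a set of them, 105 stayed within 1.5 times. These include counts of 0 at 0.1 mg/kg and between 50 and 15 mg/kg that stayed 0, which say little about stability. With only the groups compared, 11 probe sets were called at 15 mg/kg, 89 at 50 mg/kg and 199 for the trend, with fewer arrays in the fit. Adjustment over all contrasts together gave 6 at 0.1 mg/kg, 153 at 50 mg/kg, 203 for the trend and 5 between 50 and 15 mg/kg, since 1 threshold is then shared. The covariates gave 20 at 15 mg/kg, 5 lists at 15 mg/kg (the pancreas list, itself a covariate, had to drop out) and 18 shared calls, and the cause was not tested. Without arrays with muscle or pancreas transcripts, which leaves 4 vehicle arrays, 1 at 0.1 mg/kg (assumed to vary like the others), 3 at 15 and 2 at 50 mg/kg, 3 were called at 15 mg/kg, 3 at 50 mg/kg, 5 for the trend, 0 between 15 and 0.1 mg/kg, 3 shared, and 15 lists at 50 mg/kg. That fit has fewer arrays. The actin covariate gave 193 at 50 mg/kg, cause not tested. An estimated correlation left 0, 1 and 1 lists at 0.1, 15 and 50 mg/kg, and fry 0 and 3 at 0.1 and 15 mg/kg. Splitting the vehicle arrays gave 9 shared calls, with fewer arrays.

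Leaving out each array gave 0 to 1 probe sets at 0.1 mg/kg, 14 to 44 at 15, 106 to 264 at 50, 232 to 487 for the trend, 0 between 50 and 15, and 19 to 29 between 15 and 0.1 mg/kg. It gave 5 to 6, 6 to 10 and 8 to 12 lists at 0.1, 15 and 50 mg/kg, and 13 to 33 shared calls. Of 54 calls of named genes 30 held in every such fit, 18 ended without vehicle replicate 4 and 17 without replicate 4 at 50 mg/kg, and over 918 alternative fits 0 reversed.

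The replicate numbers share no stated source. Deviations of the 30 same-numbered pairs correlated between -0.36 and 0.29, 9 over 0.1, and an array matched its own number best in 4. With the replicate number as a block the counts were 36 at 15 mg/kg, 235 at 50 mg/kg, 406 for the trend and 26 between 15 and 0.1 mg/kg. With it the calls of Selenok at 15 mg/kg and of H4f3 and Ehhadh at 50 mg/kg ended, and so did that of the acute phase list at 15 mg/kg (adjusted p = 0.0510). The block for the leading digit ended the calls of Meox2 and Selenok at 15 mg/kg and of H4f3, Ehhadh and C1qc at 50 mg/kg. Of the 54 named calls 5 ended with the digit block, 5 with another quantile normalization, 3 with the intensity trend, 2 with array weights, 12 with the covariates and 50 without arrays with muscle or pancreas transcripts. Values near the background limit what can be said of dim probe sets.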

Other observations

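The other lists did not pass at 50 mg/kg. Gluconeogenesis genes had a median log2 change of -0.18 over 10 members (adjusted p = 0.0537), B cell genes -0.21 (adjusted p = 0.0626), T and NK cell genes -0.04 (adjusted p = 0.113), erythroid genes -0.35 over 12 members (adjusted p = 0.192) and hepatocyte genes -0.07 (adjusted p = 0.214). Adipose genes (adjusted p = 0.260), growth hormone and IGF genes (0.391), p53 targets (0.404), pericentral genes (0.496), immediate early genes (0.528), endoplasmic reticulum stress genes (0.560), clock genes (0.560), fetal liver genes (0.593), heat shock genes (0.706, 1 of 6 members rising), interferon response genes (0.735), endothelial genes (0.767), bile acid genes (0.797) cholangiocyte genes (0.842), cell cycle genes (0.262), stellate cell and fibroblast genes (0.384), skeletal muscle genes (0.817) and exocrine pancreas genes (0.905) did not pass either. Median and mean differed in sign for pericentral (-0.01 and 0.03), fetal liver (0.03 and -0.01) and exocrine pancreas genes (0.04 and -0.02).

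The muscle transcripts included the developmental myosin genes Myh3 and Myh8, which read 8.12 and 9.09 on replicate 4 at 0.1 mg/kg and 4.04 and 3.87 on replicate 3 at 0.1 mg/kg, chosen after their values were seen. The erythroid list mean ranged from 8.34 to 10.49 over the arrays, and Afp read 14.21 to 14.34.

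Other splits of the same arrays, planned before the data were examined, bear on each count. Of 100 splits each, 1 (the real one) gave as many probe sets at 15 mg/kg (36, highest other 1), at 50 mg/kg (290, highest other 2), between 15 and 0.1 mg/kg (28, highest other 5), for the trend (449, highest other 121) and for the shared calls (32, highest other 1), so that regrouping of the arrays did not give such counts. For 0.1 mg/kg and for 50 against 15 mg/kg the count was 0, which 100 of 100 splits reach (highest other 1 each). For the lists with the preset correlation regrouping often did: 54 of 100 splits gave as many as the 6 at 0.1 mg/kg (highest other 11), 34 as many as the 8 at 15 mg/kg (highest other 12) and 12 as many as the 9 at 50 mg/kg (highest other 14). Taken by list, 1 of 100 splits gave a p as small for the CAR and PXR, Kupffer, AhR and NRF2 lists at 50 mg/kg, against 23 for cholesterol synthesis, 22 for neutrophil, 11 for acute phase, 9 for PPARA and 3 for periportal genes.

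The tests of the 3 patterns that follow were chosen after the results were seen. The Kupffer list was lower at 50 mg/kg. A lower share of every cell type other than hepatocytes would lower endothelial markers alike, but the Kupffer mean less the endothelial mean changed by -0.431 (exact permutation p = 0.00794, below every vehicle array in 5 of 5), which argues against it. Unequal amounts of muscle, pancreas or erythroid cells are also argued against, since with these covariates the change was -0.472 (95% interval -0.692 to -0.253), against -0.440 without. Unequal amounts of granulocyte precursors or B cells, which were not in that fit, stay open, as do fewer macrophages or lower expression in them as an effect of the dose. The neutrophil and B cell lists had negative medians at 50 mg/kg. The neutrophil call did not hold with an estimated correlation (adjusted p = 0.594), and the B cell list did not pass (adjusted p = 0.0626).

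All arrays are labelled female, yet on 20 of 20 arrays every Xist probe set lay under the lower quartile and Eif2s3y lay over the median. That the RNA came from males is a candidate explanation, which these values prompted and so do not test. Probe sets that read X-linked copies together with unresponsive Xist probe sets cannot be told apart from it, because 0 arrays are labelled male. No biological explanation was tested.

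Dnajb3 rose at 50 mg/kg and neighbours the Ugt1a genes in the gene table. That its probe set reads the same transcripts as the 2 Ugt1a probe sets stays open, although Dnajb3 rose by 1.675 log2 units more than their mean (95% interval 1.178 to 2.171, exact permutation p = 0.00794), which differed by 0.219. The Ugt1a probe sets are among the brightest 5% (vehicle means 12.96 and 12.04), so that the difference may come from compression, and Dnajb3 may also read a single Ugt1a transcript that they hold in a small share. Within groups its correlation with the mean of 2 Ugt1a probe sets was a Pearson r of 0.446 (95% interval -0.045 to 0.763, permutation p = 0.0822) and Spearman rho of 0.400 (permutation p = 0.116) over 20 arrays, and r was 0.466 without the 2 arrays farthest from the median, so that such a transcript and a rise of Dnajb3 itself cannot be told apart with so few arrays and 1 relation tested. A response of Dnajb3 to the dose stays open.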
